A study of Mus musculus with 2 samples.

How the data were processed

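Total RNA of the glandular stomach of 1 wild-type and 1 Agr2 null mouse, both female per the labels, was labelled with biotin. It was hybridized to Illumina MouseRef-8 v2 bead arrays, a 1-colour platform. The deposited intensity values are linear probe signals, 1 per probe and array. The file with signals that the authors deposited as not normalized held 25697 probes with values from 70.7 to 57640, and how beads were summarised and whether background was subtracted is not given in the sources used here. The authors' processed value table held the same intensity values multiplied by a single factor per array (0.960 for the array labelled wild-type and 0.842 for the array labelled null, largest relative deviation 4.95e-10), which gave both arrays a mean of 778 and medians of 162 and 158. This was found from the values, since no header or label describes it. Its scale is linear and no gene was centred.

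The analysis started from the signals that were not normalized. The planned analysis assumed detection p-values and, where given, bead errors. The files hold neither, nor control probes, so 1314 probes for olfactory and vomeronasal receptors, chosen by symbol after the files were seen, served as background probes in their place. Background was corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, with its parameters taken from these probes and an offset of 16, followed by quantile normalization and log2. A detection p per probe and array was the share of background probes with a signal at least as high, and a gene was detected under 0.01. The background probes had median signals of 123 and 134 and a 99th percentile of 200.4 and 227 on the arrays labelled wild-type and null. They were left out of all gene results. If some of these receptors are expressed in stomach, the background is set too high and fewer genes are called detected.

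Each gene was represented by its probe with the highest mean normalized value, and detection was read from that probe. Of genes detected on 1 array, 10 had a dimmer probe detected on the other array, none of them named in the text. Of 18138 symbols in the files, 14309 matched a current mouse gene symbol of the GRCm38.p6 annotation, 2641 matched a single gene as a synonym, and 1188 kept the name in the files. A further limit of the names is 25 symbols, on 35 probes, that are plain numbers, and these were not named. On the arrays labelled wild-type and null, 8642 and 8350 genes were detected, 39 and 34 probes had signals over 40000, where signals approach the ceiling, and the 100 brightest probes held 17.2% and 15.5% of the signal.

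With 1 array per group no test of genotype was made, and no p-value or standard error is given. Genes detected on at least 1 array were counted by size, at least 2-fold higher or lower. For a gene below background on an array, the fold is given as a bound, from the bright array's value against the higher of the dim probe's own value and the lowest value among detected probes of that array, and counts and list medians are also given with such genes at their bound. Lists of genes for 39 cell types and pathways were fixed before the data were examined. For each, the median log2 difference of its detected members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and called apart under the 2.5th or above the 97.5th percentile. The named genes were also fixed by rule: Agr2, the 12 largest differences in each direction among genes detected on both arrays, the 5 largest bounds in each direction among genes detected on 1 array, up to 5 members per list with the largest differences of at least 2-fold (or, where fewer than 2 members reached it, the 2 brightest), and the 4 brightest members of the surface mucous, neck, chief, parietal and metaplasia lists, 204 genes in all, not all of which are reported here. Outside this rule, the list members Uty, Ddc, Chgb, Chrm3, Pga5, Xbp1, Atf4, Asns, Cdx2, Tff3 and Ivl were chosen after their values were seen. Members of multigene families with near-identical copies are described as uncertain.

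The steps were tested on simulated arrays made from the real probe levels and background, with noise of SD 0.2 on the log2 scale. In that simulation of the array labelled null against the array labelled wild-type, 11667 genes were tested. Of 50 genes per size, 3 were called at a true 1.5-fold difference, 27 at 2-fold, and 50 at both 3-fold and 4-fold. The changed genes were drawn only from genes well above background, so these counts do not describe dim genes. The noise was set and not estimated, for lack of replicates, and background was drawn independently for each simulated array. The share of false calls on the real arrays may therefore differ. Of 11467 unchanged genes, 743 (6.48%) were called at 2-fold, 50 of the 9254 detected on both simulated arrays and 693 of the 2213 detected on 1. Of 40 unshifted lists of 15 genes none was called apart, and of 40 lists raised by 0.5 on the log2 scale 38 were. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

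Alternatives fixed before the data were examined were no background correction, scaling to equal medians or cyclic loess in place of quantile normalization, an offset of 50, the authors' processed table, a detection p under 0.05, no detection filter, detection on both arrays, the mean over a gene's detected probes, thresholds of 1.5-fold and 3-fold, and genes below background at their bound. Background correction without the background probes was added after the data were seen. Additional gene lists used only among the closing observations were also chosen after the data were seen. No array could be left out, and no coordinates are given, since the annotation was used for names alone.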

Results

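Glandular stomachs of mice aged 26 weeks were profiled on Illumina bead arrays, on which each probe reads the abundance of a transcript as a fluorescence intensity. Per the labels the mice were female and wild-type or null for Agr2. There was 1 array per group, so no difference had a replicate check, and the number of arrays limits the precision of every value. Mean probe signal was 811 on the array labelled wild-type and 925 on the array labelled null, and median probe signal was 169 and 187. Of 16928 genes on the array, 9359 were detected on at least 1 array: 7633 on both, 1009 on the array labelled wild-type alone and 717 on the array labelled null alone. The comparison asked which stomach transcripts differ when Agr2 is lost. Agr2 is a protein disulfide isomerase relative of the endoplasmic reticulum that mucus-secreting epithelia need for mucin production.

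The targeted gene went against its label. Agr2 (NCBI gene 23795) had a signal of 972 on the array labelled wild-type and 3406 on the array labelled null, a normalized value 3.13-fold higher on the latter (log2 difference 1.64). Both signals lay above the 99th percentile of the background probes, which was 200.4 on the array labelled wild-type and 227 on the array labelled null. A single probe read Agr2, and its position relative to the deleted part of the gene is not given in the sources used here. A probe outside the deleted part would check nothing. The sex-linked genes also differed, although both samples are labelled female. Xist, the RNA of the inactive X chromosome, read 186 (below background) on the array labelled wild-type and 1774 on the array labelled null, at least 15.6-fold higher on the latter. The Y-linked genes Eif2s3y, Kdm5d and Ddx3y read 2096, 303 and 5332 on the array labelled wild-type, against 134, 119 and 2138 on the array labelled null, where the first 2 were below background. Y-linked Uty read 210 and 245, little above the 99th percentile of the background probes on each array. Over these 5 genes the median log2 difference was -1.62 (percentile 1.20 among matched random lists). A sex difference would move Xist and the Y-linked genes in opposite directions, so this median reflects only that most of the 5 are Y-linked. By the single genes, the samples may differ in sex as well as in genotype label, and 1 array per group cannot separate the 2. Because Agr2 goes against the label, arrays are named by their labels throughout, and every direction is that of the array labelled null relative to the array labelled wild-type.

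The array labelled null combined very low acid-secretion and endocrine transcripts with high transcripts of metaplasia, proliferation, protein folding and neutrophils. In all, 1227 genes were at least 2-fold higher and 1597 at least 2-fold lower. The proton pump subunits Atp4a and Atp4b were 328-fold and 181-fold lower. Cldn2, a tight junction protein, was 232-fold higher (signal 211 against 27123) and the chloride channel Cftr 70.8-fold higher (242 against 10830). The dim signals of Atp4a (265), Cldn2 and Cftr lay little above the 99th percentile of the background probes (227 on the array labelled null, 200.4 on the other). The size of such folds therefore depends on the background correction and offset. Apoa1, Rgs17, Mmp13, Calr and Hyou1 are among other genes with this limit. Signals over 40000 approach the ceiling of the array, where differences are compressed. On the array labelled wild-type this holds for Atp4a (43340), Atp4b (55622), Apoa1, Lor, Krt10, Ckb, Gif, Chia1, Ghrl, Clps and Pgc, and on the array labelled null for Gkn3, and on both for Gkn1, Gkn2 and Tff2. Genes of squamous epithelium, pancreatic acini and smooth muscle were lower as well, with list medians of -4.96, -5.60 and -3.05. With genes below background on an array taken at their bound, 1003 genes were at least 2-fold higher and 1270 lower, and without background correction 681 and 1012. The balance of the directions depended on the scaling, with 1456 higher and 1445 lower after scaling to equal medians and 1062 and 1737 after cyclic loess.

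**Figure D1:**
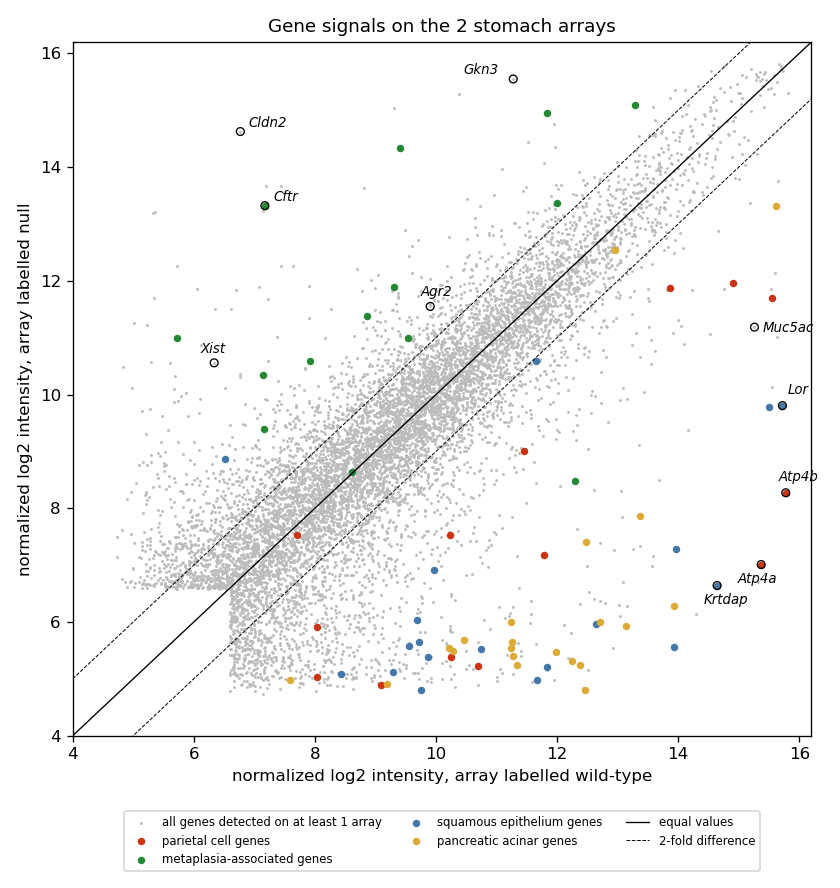
Normalized log2 intensity of each gene detected on at least 1 array, on the array labelled wild-type (horizontal) and the array labelled null (vertical), 1 array per group; coloured points are members of 4 gene lists, ringed points are single genes, and dashed lines mark a 2-fold difference. Parietal, squamous and pancreatic acinar genes lie mostly below the lower dashed line (13 of 14, 18 of 19 and 20 of 21 at least 2-fold lower) and 12 of 14 metaplasia-associated genes above the upper dashed line.

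Parietal cell genes had the lowest median of the 5 gastric cell lists. Of 14 detected, 13 were at least 2-fold lower and none was higher, with a median log2 difference of -3.43 (-2.82 with genes below background at their bound), lower than all 10000 random lists of matched expression. Besides the proton pump, the potassium channel subunits Kcnj15 and Kcne2 were lower, Kcnj15 by 24.4-fold and Kcne2 by at least 17.2-fold, and creatine kinase Ckb was 14.5-fold lower. Chrm3, a muscarinic receptor, was the member within 2-fold (-0.17). Smooth muscle (16 of 16), squamous (18 of 19) and pancreatic acinar genes (20 of 21) were at least 2-fold lower on the same array.

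Endocrine cell genes followed the parietal genes, with 10 of 12 detected members at least 2-fold lower (8 at the bound), 1 higher and a median of -2.84 (-2.63 at the bound), also below all matched random lists. Acinar, smooth muscle and squamous genes were lower on this array as well (medians -5.60, -3.05 and -4.96). Somatostatin (Sst) was 27.5-fold lower, chromogranin A (Chga) 27.4-fold and ghrelin (Ghrl) 11.1-fold. Chgb, another granin, was at least 2.05-fold higher, and Ddc was within 2-fold. Nerve and glia genes were lower too, with 6 of 8 at least 2-fold lower (3 at the bound), 1 higher (none at the bound) and a median of -2.28 (-0.71 at the bound, percentile 0). The neuropeptide gene Vip was 7.78-fold lower, the neuronal gene Stmn2 was at least 2.45-fold lower, and the glial gene S100b was at least 1.74-fold higher. This list no longer stood apart without the detection filter (median -0.15).

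Chief cell genes did not move as a block. Intrinsic factor (Gif) was 24.6-fold lower and the acidic chitinase Chia1 42.7-fold lower, but the pepsinogen Pga5 was within 2-fold (3542 against 3491), and Bhlhb8, the zymogenic transcription factor also called Mist1, was 3.504-fold higher. The pepsinogen Pgc read 50462 and 38866, near the ceiling on the array labelled wild-type and close to it on the other. Of 8 detected members 4 were lower, 1 was higher and 3 were within 2-fold, with a median of -1.28 (percentile 0.01). Clps, at 4.90-fold lower, is also on the pancreatic acinar list, whose genes were lower on the same array. Without the detection filter the list median was -0.31 and no longer apart from random lists.

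Mucous cells showed a split between genes. Among 12 surface mucous cell genes, 1 was higher, 3 were lower and 8 were within 2-fold, and the median of 0.21 was within the range of random lists (percentile 72.2). The secreted mucin Muc5ac was 16.8-fold lower (39881 against 2670), whereas Gkn1 and Gkn2 differed by 0.23 and 0.25 on the log2 scale, with signals near the ceiling on both arrays. Of 6 mucous neck cell genes 3 were higher and none was lower (median 0.97, percentile 99.6). Gkn3 was 19.4-fold higher (2368 against 47368), A4gnt, which adds a sugar cap to gland mucin, was at least 5.01-fold higher by the brighter of its 2 detected probes (1.57 and 2.55 on the log2 scale), and the gland mucin Muc6 was 2.12-fold higher. Tff2, the spasmolytic polypeptide, was near the ceiling on both arrays (45896 and 46750).

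Metaplasia-associated genes were higher, with 12 of 14 detected members at least 2-fold higher, 1 lower and a median of 2.55, above all 10000 matched random lists. The same array had lower smooth muscle, squamous and acinar genes (medians -3.05, -4.96 and -5.60) and higher neutrophil genes (median 2.72). Besides Cftr, the immunoglobulin transporter Pigr was 30.5-fold higher, the water channel Aqp5 9.22-fold, the scavenger receptor Dmbt1 8.68-fold and the progenitor transcription factor Sox9 6.37-fold. Wfdc2, often used as a marker of this metaplasia, went the other way and was 14.1-fold lower. Lcn2, at least 21.1-fold higher, is also on the neutrophil list, and Cd14 (5.73-fold higher) on the macrophage list. Intestine-type genes went both ways. Of 15 detected, 7 were higher and 6 lower (5 at the bound), and the median of 0.94 (percentile 99.95) lay between these opposed members. Clca3 was 30.0-fold higher and Reg3g and Reg3b at least 38.3-fold and 30.2-fold higher, while the apolipoproteins Apoa1 and Apoa4 were 393-fold (41749 against 237, near the ceiling) and at least 17.3-fold lower and the goblet cell peptide Tff3 was at least 11.3-fold lower. The intestinal regulator Cdx2 was at least 1.13-fold lower. Reg3 and Clca genes belong to families of similar sequence, so their values are uncertain, and without the detection filter the median was 0.21 and not apart from random lists.

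Among 17 gastric and foregut transcription factor genes, 5 were higher, 1 was lower and 11 were within 2-fold (median 0.27, percentile 85.8). The antral and duodenal factor Pdx1 was 3.78-fold higher, Foxa1 3.36-fold, Sox21 3.27-fold and Spdef, a regulator of mucous secretory cells, 2.62-fold higher, whereas Barx1, a factor of stomach mesenchyme, was 3.62-fold lower. Averaging over probes put this list apart from random lists (0.51).

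Protein folding genes were higher on the array that also had the higher Agr2 signal, the higher plasma cell genes (median 2.25) and the lower smooth muscle, squamous and acinar genes (medians -3.05, -4.96 and -5.60). Of 25 detected endoplasmic reticulum chaperone and folding genes, 11 were at least 2-fold higher (9 at the bound) and none was lower (median 0.99, or 0.78 at the bound, above all matched random lists). The co-chaperone Dnajb9 was 5.96-fold higher, calreticulin (Calr) 4.98-fold and Hyou1 4.30-fold, whereas Xbp1, the transcription factor of the unfolded protein response, was within 2-fold (-0.35). Protein disulfide isomerase relatives of Agr2 shared 7 detected members with that list. Of 13 detected, 5 were higher (4 at the bound) and none was lower (median 0.87, or 0.66 at the bound, percentile 99.9), led by Pdia5 at 5.21-fold and Pdia4 at 3.87-fold. Genes of the Atf4 and Chop arm of the stress response had a lower median but were mixed. Of 16 detected, 5 were lower (4 at the bound), 1 was higher and 10 were within 2-fold (median -0.65, percentile 0.33). Ddit3, which encodes Chop, was 2.86-fold lower and Chac1 2.49-fold lower, while the cystine transporter Slc7a11, shared with the metaplasia list, was 4.70-fold higher. Atf4 itself was within 2-fold (0.61) by the brighter of its 2 detected probes, and the other gave 1.58. Asns differed by -0.02 by its brightest probe, but its 3 detected probes reached 2.61. The Atf4 and Chop list was no longer apart without the detection filter (-0.37) or over genes detected on both arrays (-0.33).

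Proliferation genes were higher as a group, on the array where smooth muscle (16 of 16), squamous (18 of 19) and acinar genes (20 of 21) were lower and neutrophil and plasma cell genes (medians 2.72 and 2.25) higher. Of 29 detected cell cycle genes, 18 were at least 2-fold higher (15 at the bound) and none was lower, with a median of 1.14 (1.05 at the bound), above all matched random lists. Prc1, which organizes the mitotic spindle midzone, was 12.5-fold higher, topoisomerase Top2a 4.42-fold, Cdc20 4.35-fold and Cdk1 3.70-fold. Of 7 epidermal growth factor receptor ligand and receptor genes, 5 were higher (4 at the bound) and 1 was lower (median 1.08, percentile 99.7). The ligands Areg, Btc and Hbegf were 3.28-fold, 3.22-fold and 2.80-fold higher, and Egf was at least 5.35-fold lower. Of 8 Wnt target and stem cell genes, 4 were higher and 1 was lower (median 0.66, percentile 96.8). Ephb2 was 4.27-fold higher and Ccnd1 2.98-fold higher, Sox9 and Cd44 are shared with the metaplasia list, and Tnfrsf19 was at least 3.87-fold lower. Of 8 Hippo-Yap target genes, 3 were higher and 1 was lower (median 0.64, percentile 96.8), with Ccn1 2.27-fold higher and the receptor Axl 4.18-fold lower. Both lists were within the random range here and apart from it under several alternative settings. Hedgehog and Bmp pathway genes had 4 of 10 members lower and 1 higher (median -0.49, percentile 5.70), with Bmp4 3.10-fold lower and Ihh 2.04-fold higher. Notch pathway genes had 2 of 8 lower and 1 higher (median -0.22, percentile 28.1), with Hes1 2.65-fold higher.

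Neutrophil genes and inflammatory mediators were high. Of 8 detected neutrophil genes 7 were at least 2-fold higher (6 at the bound) and none was lower (median 2.72, above all matched random lists). The calcium-binding proteins S100a8 and S100a9 were 67.4-fold and 7.39-fold higher, Retnlg was at least 14.8-fold higher and lactoferrin (Ltf) 5.85-fold higher. Among 21 cytokine and chemokine genes, 14 were higher (8 at the bound) and 2 lower (1 at the bound), with a median of 1.67 (0.55 at the bound). The acute-phase gene Saa3 was at least 50.6-fold higher, and interleukin 1 beta (Il1b) and the neutrophil chemokine Cxcl1 were at least 11.4-fold and 11.3-fold higher, while the lymphoid chemokine Ccl21a was 14.8-fold lower. Most of the higher members were below background on the array labelled wild-type, and over genes detected on both arrays the median was 0.10 and not apart from random lists. Plasma cell genes had 3 of 5 members higher and none lower (median 2.25, or 2.02 at the bound, percentile 100), with Mzb1 4.75-fold and the B cell coactivator Pou2af1 at least 5.11-fold higher. Their median was 0.40 over genes detected on both arrays and 0.36 without the detection filter, in neither case apart from random lists.

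Other immune groups were lower or near level. Of 26 interferon response genes, 14 were at least 2-fold lower (10 at the bound) and none was higher (median -1.10, or -0.63 at the bound, percentile 0.02), with Oas2 13.5-fold, Usp18 7.78-fold and Rsad2 7.59-fold lower. Macrophage and dendritic cell genes had 4 of 16 members lower and 1 higher (median -0.63, percentile 1.11). The scavenger receptor Cd163 was at least 4.93-fold lower and Csf1r 2.08-fold lower. Among mast cell and eosinophil genes, the tryptase Tpsb2 was 3.25-fold lower and the tryptase Tpsab1 at least 13.3-fold lower, while the proteases Mcpt1 and Mcpt4, of mucosal and connective tissue mast cells, were 3.94-fold and 3.54-fold higher. Of 9 members 5 were lower and 2 higher (median -1.16, percentile 0.67), and Hdc is shared with the endocrine list. Without the detection filter neither list stood apart (-0.31 for macrophages and -0.11 for mast cells). All 6 class II histocompatibility genes were within 2-fold (median -0.68, percentile 3.15), among them Cd74 at -0.76, and all 3 detected T and B lymphocyte genes were within 2-fold (median 0.64, or 0.10 at the bound, percentile 82.4), with Cd3e at -0.47.

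Squamous, pancreatic acinar and smooth muscle genes had higher signals on the array labelled wild-type. Of 19 detected squamous epithelium genes, which the forestomach expresses, 18 were at least 2-fold lower on the array labelled null (median -4.96, or -3.29 at the bound). Lor, a cornified envelope protein, read 54602 against 1114, Krt10 46758 against 1103 and Krtdap 23897 against 232. Ivl, another envelope protein, was at least 4.82-fold higher. Of 21 pancreatic acinar genes 20 were at least 2-fold lower (median -5.60, or -4.69 at the bound), with the lipase relative Pnliprp1 at least 164-fold, the elastase Cela2a at least 94.0-fold and the lipase Pnlip at least 55.7-fold lower. All 16 smooth muscle genes were at least 2-fold lower (15 at the bound, median -3.05, or -2.69 at the bound), among them Mylk (10.6-fold), Myh11 (9.37-fold) and Tagln (8.91-fold). The medians of these 3 lists lay below all matched random lists. Trypsin, elastase and amylase genes have near-identical copies, so their single values are uncertain.

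Connective tissue, vessel, fat and blood genes were lower by smaller amounts, on the array that also had the lower smooth muscle signal. Fibroblast and matrix genes had 7 of 21 members lower and 2 higher (median -0.63, percentile 0.20), with Fbln1 5.16-fold lower and Timp1, an inhibitor of matrix proteases, 3.46-fold higher. Endothelial genes had 3 of 13 lower (2 at the bound) and 1 higher (median -0.67, percentile 1.23), with the lymphatic receptor Lyve1 4.72-fold lower and the angiopoietin receptor Tek 3.73-fold higher, and without the detection filter their median was -0.15 and not apart. Adipocyte genes had 4 of 9 lower and 1 higher (median -0.91, or -0.90 at the bound, percentile 0.71), with Lpl 36.2-fold lower and adipsin (Cfd) at least 49.9-fold lower. All 4 detected erythrocyte genes were at least 2-fold lower (2 at the bound, median -1.50, or -0.93 at the bound, percentile 1.69), including Hba-a1 at 3.67-fold, a globin with a near-identical copy.

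Nuclear genes of the mitochondrial respiratory chain had 9 of 57 members lower and 1 higher (median -0.56, below all matched random lists). Cox7a1, the muscle isoform of a cytochrome oxidase subunit, was at least 88.2-fold lower and Ndufb10 5.01-fold lower, on the array where parietal and smooth muscle genes were lower too. Ribosomal protein genes had 6 of 46 higher and none lower (median 0.34, percentile 99.6), with Rpl7a and Rpl30 each 3.52-fold higher. Of 24 oxidative stress and glutathione genes, 8 were higher (7 at the bound) and 3 lower (median 0.45, percentile 99.05). Gsta3 was 7.58-fold higher, and both subunits of glutamate cysteine ligase, Gclm and Gclc, were 4.32-fold and 3.02-fold higher, as was the quinone reductase Nqo1 (3.63-fold). With genes at their bound this list was no longer apart (0.35). Heat shock genes had 3 of 10 lower and 1 higher (median -0.31, percentile 9.65), with Hspb1 7.27-fold lower and Hspa8 8.05-fold higher. Immediate early genes had a median of 0.00 (percentile 47.9), of a sign that changed between scalings, with 2 of 15 higher (1 at the bound; Egr2, at least 1.69-fold, and Socs3, 2.60-fold) and none lower.

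**Figure D2:**
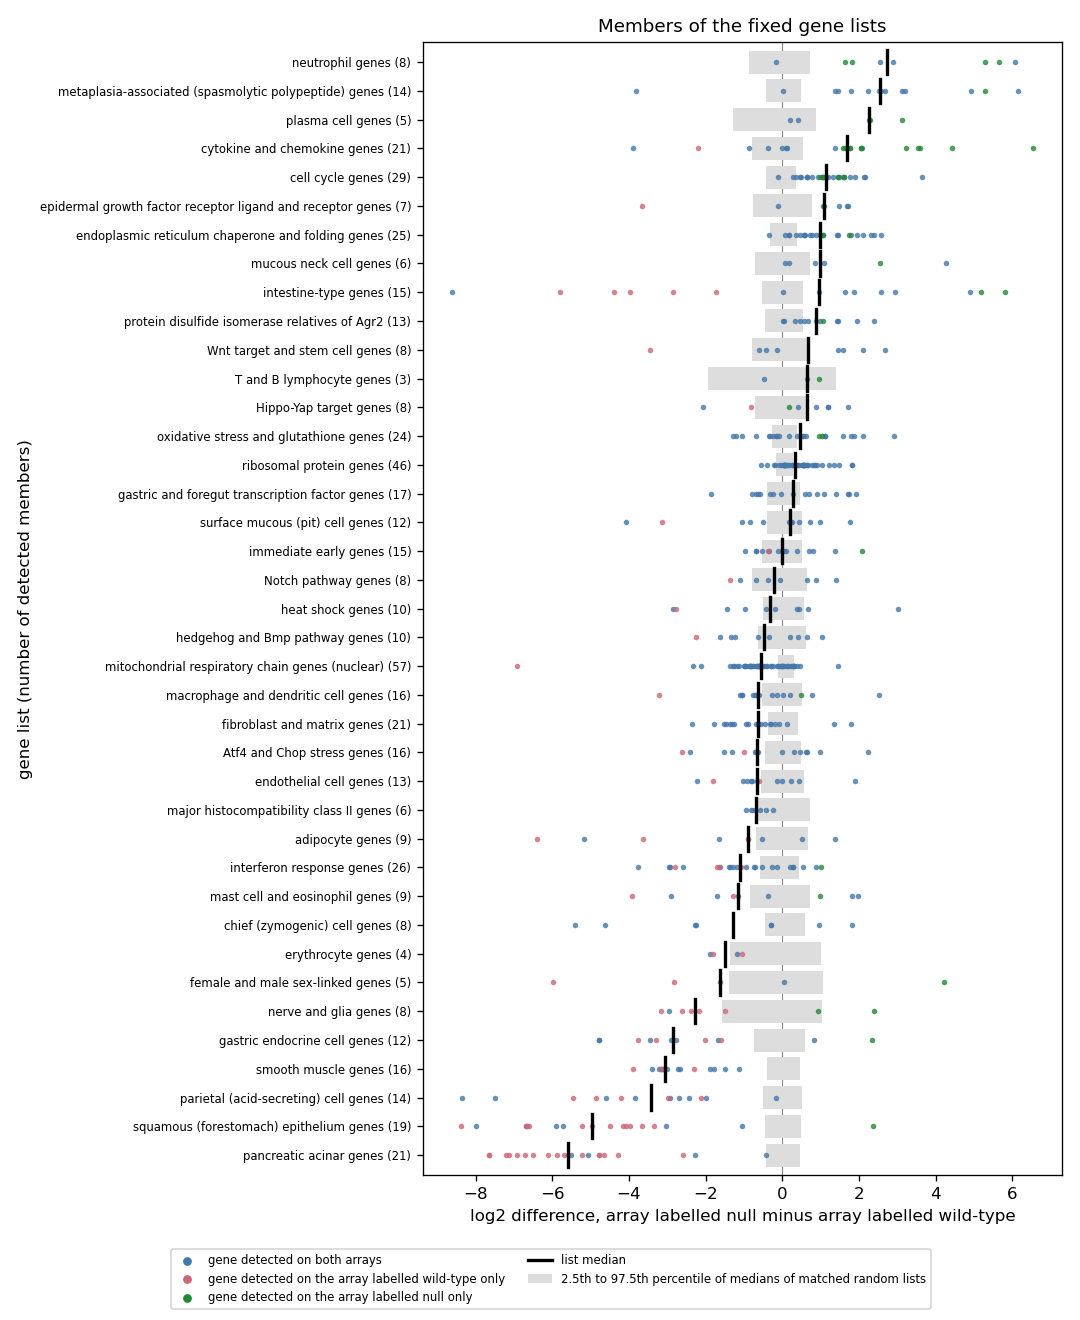
Log2 difference, array labelled null minus array labelled wild-type, of the detected members of each of 39 gene lists (points, coloured by the arrays that detected the gene), with the list median (black bar) and the range of medians of 10000 matched random lists outside which a list was called apart (grey), 1 array per group. The medians of 12 lists lie above the grey range, from neutrophil genes at 2.72 down to ribosomal protein genes at 0.34, and those of 17 lists below it, down to pancreatic acinar genes at -5.60.

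Of the 12 genes detected on both arrays that were lowest, 9 are expressed in cornified or squamous epithelium (Krtdap, Krt13, Asprv1, Crct1, Lce1d, Dmkn, Rptn, Lor and Krt10), from 256-fold lower for Krtdap to 52.6-fold for Krt10, and Apoa1, Atp4a and Atp4b are the others. The 3 detected probes of Dmkn ranged from -6.17 to -1.75, and Lce1d belongs to a family of similar copies. Below background on the array labelled null were Hamp2, a hepcidin gene (at least 209.9-fold lower), Krt14 (at least 163-fold) and Lce1f (at least 95.6-fold), besides Pnliprp1 and Cela2a. In the other direction, surfactant protein D (Sftpd) was 89.2-fold higher, the secretory androgen-binding protein gene Abpb, of a family of similar copies, 74.8-fold, LOC100043836 53.1-fold, the collagenase Mmp13 35.0-fold (its 3 detected probes from 0.96 to 5.13), Rgs17 29.7-fold, Onecut2 28.3-fold and the chitinase-like gene Chil4 28.1-fold. Genes below background on the array labelled wild-type included Chil3 (at least 97.9-fold higher, its 3 detected probes from 3.82 to 7.85 on the log2 scale), Wfdc18 (at least 97.2-fold) and the matrix protease Mmp10 (at least 34.5-fold). Chil3 and Chil4 are near-identical and uncertain as single values.

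Chance alone would put about 2 of 39 lists apart, against 29 here, but genes of a list are not independent of each other. The percentiles describe the 2 arrays and not the genotypes, and the 29 include the sex-linked list, whose median mixes genes of opposed direction. The SD of the log2 difference between probes of a gene was 0.30 at the median of 1555 genes and 0.50 pooled. Of these 1555 genes, 3 had probes that were 2-fold in opposite directions. Among the genes counted at 2-fold, 291 had several probes detected on both arrays. Of these 291, 270 had all such probes of the same sign and 169 had all of them at 2-fold, so many counts rest on the brightest probe. The detected probes of Chga ranged from -5.20 to -3.77, of Mylk from -3.40 to -2.69, of Cdc20 from 0.78 to 2.17, of Ltf from 1.37 to 2.55, of Nqo1 from 0.85 to 1.86, of Pdia5 from 1.79 to 3.20 and of Reg3b from 3.80 to 5.17. The median log2 difference of all genes was 0.00, and 0.12 with scaling to equal medians.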

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

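Every alternative was planned except background correction without the background probes, which was chosen after seeing the data. No list that stood apart and no named gene at 2-fold reversed its direction, while the median of immediate early genes, not apart, ran from -0.13 to 0.11. Of all genes at 2-fold, 4 changed sign with the mean over probes and 1 with correction without the background probes. Agr2 was higher on the array labelled null under all settings, by 1.53 to 1.76 on the log2 scale. No paired analysis was possible because each group had 1 array and no test was run, and for the same reason no array could be left out. Signal over background limits the dim genes: simulated unchanged genes reached 2-fold in 0.54% of cases where both arrays detected them and 31.3% where 1 did. These shares hold for a simulated noise of SD 0.2, which was not estimated from these arrays. Background was also drawn independently for each simulated array, which leaves out any background that a probe shares across arrays. The real share for genes detected on 1 array may therefore differ. Of the 29 lists apart from random lists, 19 were so under every setting that gave a value and 10 lost the call under at least 1; of the other 10, 5 were apart under at least 1. Detection on both arrays left fewer than 3 members of the T and B lymphocyte, nerve, erythrocyte and sex-linked lists, so these have no value there. Of alternative values of named genes, 1912 kept their side of 2-fold and 61 fell short of it, 19 of these with the authors' table and 16 without background correction. The counts of genes at least 2-fold higher and lower were 681 and 1012 without background correction, 801 and 933 with the authors' table (the same signals, only scaled), and 808 and 816 over genes detected on both arrays, where fewer genes were counted. Their balance depended on the scaling, with 1456 and 1445 after scaling to equal medians and 1062 and 1737 after cyclic loess. They were 2281 and 2448 at 1.5-fold and 520 and 909 at 3-fold. Lists that lost their call without the detection filter, which adds genes at background, had medians there of -0.37 (Atf4 and Chop), -0.31 (chief), -0.15 (endothelial), 0.21 (intestine-type), -0.31 (macrophage), -0.11 (mast cell), -0.15 (nerve) and 0.36 (plasma cell). The Notch (-0.33) and T and B lymphocyte (0.28) lists gained one there. Over genes detected on both arrays, Atf4 and Chop (-0.33), cytokine (0.10), oxidative stress (0.26) and plasma cell genes (0.40) lost the call and Hippo-Yap (1.03) and Wnt genes (1.45) gained it. Hippo-Yap genes were also apart with the authors' table (0.61), genes at their bound (0.64), no background correction (0.53), no background probes (0.62) and an offset of 50 (0.63), and Wnt genes with the authors' table (0.69), no background correction (0.60) and no background probes (0.63). Mast cell genes lost the call at a detection p under 0.05 (-0.77), oxidative stress genes lost it at their bound (0.35), and gastric transcription factor genes gained it with the mean over probes (0.51). Beyond the filters and bounds, whose construction changes the genes or values entered, the cause was not tested.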

Other observations

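The oxidase, claudin, chitinase, liver, islet and skeletal muscle lists, and all tests of explanations, were chosen after the data were seen, so these lists only describe genes. For the forestomach, type 2 cytokine and clock hypotheses, also raised by signals already seen, the predictions were written before the test values were looked at. Agr2, the parietal, mucous, squamous and acinar lists and all settings except correction without the background probes were fixed before. Directions are those of the array labelled null relative to the array labelled wild-type, and Agr2 goes against these labels. Of 6 detected Nadph oxidase genes 4 were at least 2-fold higher and none was lower, with a median log2 difference of 1.89 (1.18 with genes below background at their bound). Cyba and Ncf4, among the 6, also serve the phagocyte oxidase, on an array with high neutrophil genes. Noxo1, the organizer subunit of the colonic oxidase, read 234 on the array labelled wild-type and 4263 on the array labelled null (log2 difference 4.81). The catalytic subunits Nox1 and Duox2, which make superoxide or hydrogen peroxide at mucosal surfaces, were below background on the array labelled wild-type and read 339 and 572 on the array labelled null.

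Claudins, the sealing and pore-forming proteins of tight junctions, did not share the difference of Cldn2 (7.86). Of 11 detected, 3 were at least 2-fold higher and 2 lower (1 at the bound, median 0.25). Cldn23 and Cldn7 were higher by 2.04 and 1.95 on the log2 scale, Cldn18, the main gastric claudin, differed by 0.17, and Cldn15 by -1.12. Chitinase and chitinase-like genes had 3 of 5 members higher and 1 lower (median 2.43, or 1.66 at the bound), of which Chil3 and Chil4 had prompted the list. Chia1, which degrades chitin in the stomach, read 48795 and 1352, whereas Chil1, Chil3 and Chil4, relatives without chitinase activity, read 162, 140 and 509 on the array labelled wild-type and 466, 10036 and 13656 on the array labelled null. Liver genes had 4 of 10 members detected and 3 lower (2 at the bound, median -2.84, or -1.29 at the bound), with albumin (Alb) below background on both arrays. Of 3 detected genes of the islet list 1 was lower (median -0.19). It was Ttr (13643 against 4137), which encodes a carrier protein and not a hormone, while Iapp and Pyy were within 2-fold. Of 2 detected skeletal muscle genes 1 was lower (median -1.89, or -1.24 at the bound).

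Agr2 was higher on the array labelled null. Scaling and background handling did not produce this, since the smallest log2 difference over all settings was 1.53. A swap of both labels, with a probe that reads the deleted part, would leave the dimmer array at background, but its signal was 4.85 times the 99th percentile of the background probes (14.99 times on the other array). A transcript of the null allele that the probe still reads, or a wrong label of another kind, may explain the signal, but with 1 Agr2 probe on the array this stays open. Y-linked Eif2s3y and Kdm5d were above background on the array labelled wild-type alone, and Ddx3y and Uty on both arrays (2138 and 245 on the array labelled null). Xist was below background on the array labelled wild-type (186) and read 1774 on the array labelled null. These values argue against the female label of the sample labelled wild-type. For the sample labelled null, Xist, Eif2s3y and Kdm5d go with the female label. The Ddx3y signal does not, although its 3 detected probes were all lower there (log2 differences from -2.94 to -1.62). Uty lay little above the 99th percentile of the background probes (227 on the array labelled null), so its signal tells little. Which mice the samples came from stays open as well, and no biological explanation was tested.

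Parietal cell genes were lower on the array labelled null. Scaling and background handling did not produce this, with list medians from -3.56 to -2.73 over all settings. Other tissue diluting the epithelium of the sample labelled null would lower the mucous genes alike. The 18 detected surface mucous and neck genes had a median of 0.24 (quartiles -0.36 and 0.96). The 11 of them without a signal over 40000 on either array, where differences are compressed, had a median of 0.44 (quartiles -0.33 and 1.04). Parietal and mucous genes therefore did not fall alike, as dilution alone would require. These values are relative to an array with high squamous, acinar and smooth muscle signal, and 3 of 6 neck genes were higher. They cannot show that the sample labelled null was free of dilution. Antrum, which has few parietal cells, may have been sampled in place of corpus: gastrin, its marker, was below background on both arrays (216 on the array labelled null and 126 on the array labelled wild-type), so this stays open, and Pdx1 was higher by 1.92. The genotype, at the age studied, is also an open explanation, as are the sex of the samples and any difference that the doubt about the labels allows.

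Squamous and pancreatic enzyme genes were high on the array labelled wild-type. The pattern was seen in 18 of 19 squamous genes, led by Lor (54602) and Krt10 (46758), and 1 went the other way. That the sample held forestomach was tested on other squamous genes not looked at before. Their 14 detected members had a median of -1.81 on the array labelled null relative to the other, at percentile 0 of matched random lists, with 11 at least 2-fold lower (10 at the bound) and 2 higher (Anxa8 and Ly6d). Genes of the same epithelium tend to vary together, so this result was likely after the first list and is not independent of it. The sample may have held forestomach, although the labels name glandular stomach, but these genes cannot tell forestomach from other squamous epithelium. Pancreas tissue may have been included too, with 20 of 21 acinar genes at least 2-fold higher there, led by Clps (51156), which the chief cell list also holds, and Pnliprp1 (14823). The insulin genes, which pancreas tissue would bring in its islets, were below background there (153 and 137), so a piece of pancreas and expression of these enzymes by the stomach itself cannot be told apart. Loss of these signals through the genotype was not tested, since 1 array per group cannot separate genotype from dissection.

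High chitinase-like, Clca3 and Il1rl1 signals on the array labelled null raised the hypothesis of a type 2 cytokine response. Of genes known to respond to such cytokines and not looked at before, 6 were detected, with a median of 0.41 at the 83.5th percentile of matched random lists, so the hypothesis was neither met nor excluded. Itln1 and Pla2g4c were detected only on the array labelled null, whereas Retnla and Arg1 were lower by at least 2-fold (-2.02 and -1.23).

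Dbp, an output gene of the circadian clock, was lower on the array labelled null (log2 difference -3.55), which raised the hypothesis that the samples were taken at different clock phases. The 5 detected genes in phase with Dbp had a median of -1.91 (-1.85 at the bound) and were all lower, among them Per1 (-1.91) and Tef (-1.96), and both detected genes in antiphase were higher (Arntl 0.79 and Clock 0.12, median 0.45). These values are consistent with different clock phases, but 2 antiphase genes with small differences are weak evidence, and hours of collection are not given in the sources used here.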
